A study of Astyanax mexicanus with 6 samples.

How the data were processed

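Liver of the Mexican tetra, Astyanax mexicanus, was profiled by RNA sequencing in 3 populations with 2 libraries each: Surface, the river-dwelling form with eyes, and Pachon and Tinaja, eyeless forms named after the caves they live in. RNA was purified with a column kit, polyA RNA was selected and strand-specific libraries were made, per the labels' protocols. The labels do not say whether the libraries of a population came from separate fish, so p-values measure only the spread between these samples, which may be technical. Sex, age, feeding and time of sampling are not given in the sources used here.

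The deposited table holds whole-number read counts per gene for the 6 libraries, which the authors left unnormalised as far as the values show: library totals differ and no value is fractional. The submitters' processing notes name bcl2fastq 2.20, which turns sequencer output into reads, and STAR, a spliced aligner, with no version. The name of the deposited count table points to build 2 of the genome assembly and to Ensembl release 96. The read counter, its strand setting and its treatment of reads that fit several genes are not given in the sources used here, so counts of near-identical gene copies, overlapping genes and antisense genes are uncertain. Coordinates were not used here.

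The table lists 27420 Ensembl gene identifiers and no gene names. The reference table used here, made for the later assembly AstMex3_surface, has no Ensembl identifiers to match, and 0 of the identifiers could be paired with a symbol. The 38 gene lists fixed before the data were examined, covering liver metabolism, immunity and markers of other cell types, could therefore not be tested, and no pathway or cell type is described. The rule for named genes, also fixed before the data were examined, asked for a symbol. For each comparison it took, among called genes with both libraries of one population above both of the other in CPM, those with the highest and lowest log2 fold changes at a mean of at least 10 CPM in the higher group, and those with the largest rise and fall in mean CPM. It was applied without the symbol and with 1 gene per direction and criterion. For the mean of both caves the fixed rule asked for genes called against Surface in both caves. Here any gene called for that mean could be taken. Of the differing genes chosen so, 4 are printed by identifier, the others by their rank; 3 abundant genes that passed no test are printed as well and were chosen after their values were seen.

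From the counts, R 4.3.3 and edgeR 4.0.16 were used to compute TMM factors, which scale libraries on the assumption that most genes do not change, and to leave out genes with too few reads (edgeR's filter by expression with a count minimum of 10). The filter kept 15282 genes, which held 99.95% of the reads; 12138 were left out, of which 5173 had no read in any library. All 6 libraries entered one model with a term per population, which left 3 residual degrees of freedom, and each comparison was tested with edgeR's robust quasi-likelihood F-test (two-sided). P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and a gene is called when its adjusted p is below 0.05. The comparisons were Pachon with Surface, Tinaja with Surface, the mean of both caves with Surface, and Pachon with Tinaja; the last is also the test of whether both caves differ from Surface by unequal amounts. The common biological coefficient of variation was 25.1%. Standard errors belong to log2 fold changes and are approximate. They were back-calculated as the size of the log2 fold change divided by the square root of the F statistic. SD is the spread between 2 libraries. CPM are counts scaled to the size of the TMM-scaled library.

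Library totals ran from 22168622 to 29521610 counts. A gene counts as off in a population with at most 3 reads over both libraries and as on with at least 1 CPM in each. A ratio against 1 read is that of the reads pooled over the libraries of each side, divided by their summed scaled library sizes, and has an exact 95% binomial interval on the counts; a bound against 0 reads uses a floor of 3 reads over the population. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Genes were grouped by mean CPM over the 6 libraries, a grouping chosen after the data were seen.

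The test was run on simulated counts with 200 genes changed by known amounts, 5 times per comparison. For Pachon against Surface it recovered 7% of genes changed 2-fold and 71.6% of those changed 4-fold on 14805 to 14943 genes tested, and 11.9% of its calls were false. For Tinaja against Surface it recovered 8.8% and 70.4% on 14889 to 14913 genes, and 12% of the calls were false. The false share was above the nominal 5%. Over their 5 simulations these runs made 446 calls for Pachon and 450 for Tinaja, against 2585 and 2411 in the data. With so few genes changed, the adjusted threshold was stricter than in the data. The recovered and false shares may therefore not carry over to the data.

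Because both cave comparisons use the same Surface libraries, 20 simulations of unchanged groups were run. All 6 libraries, Surface included, were drawn from the same mean per gene, with noise independent between genes. They show the agreement that a shared, simulated Surface group gives. Replicate differences that many genes share were not modelled. Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scaling factors, other low-count filters, a fit of only the populations compared, the replicate number as a block, a stricter threshold, a 2-fold bound, the 20 most abundant genes left out, and each library left out in turn. Total-count scaling was added after the scaling factors were seen. With 1 library of a population left out, the lone library is assumed to vary like the other groups.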

Results

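The data were gene counts from 6 liver libraries of Astyanax mexicanus, with n = 2 for each of Surface, Pachon and Tinaja. Total counts were 29521610 and 24702895 in Surface 1 and 2, 24809335 and 25945144 in Pachon 1 and 2, and 24865389 and 22168622 in Tinaja 1 and 2. Between 18361 and 19332 genes had at least 1 count in a library. The single most abundant gene took from 4.1% of the counts in Pachon 1 to 15.77% in Tinaja 2, and the 20 most abundant genes of a library took from 26.5% in Pachon 2 to 48% in Tinaja 2.

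Liver expression separated the 3 populations. The first principal component, with 46.5% of the variance, placed the Surface libraries at 86.8 and 86.5 and the 4 cave libraries between -44.2 and -42.6. The second, with 35.5%, placed Pachon at -60.9 and -68.8, Tinaja at 55 and 75.5, and Surface at 0.3 and -1.1. Spearman's rho across genes, which are not independent replicates, was 0.968 to 0.978 between libraries of a population. It was 0.896 to 0.905 between Pachon and Surface, 0.894 to 0.904 between Surface and Tinaja, and 0.9 to 0.931 between Pachon and Tinaja. As a check for duplicate libraries, the chi-square per degree of freedom between the counts of 2 libraries was 167.1 to 224.4 within populations and 172.9 to 1010.9 between them, and none was counted as a duplicate.

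Pachon and Surface livers, compared to find transcripts that differ between a cave and a river population, differed in 2585 of 15282 genes (16.9%), 1345 higher and 1240 lower in Pachon. Among called genes the median size of the log2 fold change was 1.67 (median SE 0.31), and 300 genes were at least 8-fold higher and 295 at least 8-fold lower. The higher genes took 7.7% of the counts in Pachon against 1.3% in Surface, and the lower genes 11.1% against 26.2%. ENSAMXG00000015502, highest by fold, had 148.8 CPM ± 39.8 (SD, n = 2) in Pachon and 1 read over both Surface libraries, a ratio of 6828 with a counting interval of 1225 to 269737 (edgeR adjusted p = 0.000575). Its fitted log2 fold change, which depends on the prior count, was 12.46, against 11.55 without Surface 1 and 14.94 without Surface 2. Among called genes that met the rule for named genes, ENSAMXG00000025561 rose most in CPM, from 87.5 ± 37.9 to 11324.6 ± 1439 (SD, n = 2). Its log2 fold change was 7.02 ± 1.09 (SE, edgeR adjusted p = 0.00965). ENSAMXG00000042564 fell most by fold, from 4380.0 CPM ± 530.2 to 1.13 ± 0.342 (SD, n = 2), by -11.92 ± 0.82 (SE, edgeR adjusted p = 0.000457). The second most abundant gene of the table fell by more CPM than the next gene but was not called in Pachon (edgeR adjusted p = 0.0753). Of the called genes under the same rule, the one with the largest fall in CPM went from 23386.9 ± 4536.3 to 6562.2 ± 675.7 (SD, n = 2). This gene had a log2 fold change of -1.83 ± 0.36 (SE, edgeR adjusted p = 0.0146). Its edgeR adjusted p was 0.105 without Pachon 1, 0.151 without Pachon 2 and 0.0594 without Surface 1 (highest over its alternatives 0.151), and that of ENSAMXG00000025561 was 0.0558 without Surface 1, its highest. The count of called genes was 1078 without Pachon 1, 937 without Pachon 2, 1432 without Surface 1 and 1532 without Surface 2. With total-count scaling, which moved the median log2 fold change of all genes to 0.55, 4599 genes were called, 3928 higher and 671 lower, so that 85.4% were higher against 52% with TMM.

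Tinaja livers differed from Surface livers in 2411 genes (15.8%), 1241 higher and 1170 lower in Tinaja. The median size of their log2 fold change was 1.68 (median SE 0.32), with 295 genes at least 8-fold higher and 276 at least 8-fold lower. Higher genes took 5.1% of the counts in Tinaja against 1.1% in Surface, and lower genes 8.2% against 29.4%. ENSAMXG00000015502 was again highest by fold, at 59 CPM ± 35 (SD, n = 2) against 1 Surface read, a ratio of 2947 with a counting interval of 529 to 116458 (edgeR adjusted p = 0.000871). The fitted log2 fold change was 11.13, against 10.22 without Surface 1, 13.61 without Surface 2 and 10.33 without Tinaja 1. Among called genes that met the rule for named genes, ENSAMXG00000025561 again rose most in CPM, to 6394.7 ± 6813.8 (SD, n = 2). ENSAMXG00000038452, described below, rose by more CPM but was not called (edgeR adjusted p = 0.142). The log2 fold change of ENSAMXG00000025561 was 6.19 ± 1.05 (SE, edgeR adjusted p = 0.0145). This value was 4.16 without Tinaja 1 and 7 without Tinaja 2. ENSAMXG00000038681 was lowest by fold, at 5666.6 CPM ± 2397 in Surface and 0.701 ± 0.262 in Tinaja (SD, n = 2), a log2 fold change of -13 ± 0.68 (SE, edgeR adjusted p = 0.000287). The largest fall in CPM was in the second most abundant gene of the table, from 75128.2 ± 14031.3 to 25758.2 ± 8598.8 (SD, n = 2), by -1.54 ± 0.41 (SE, edgeR adjusted p = 0.0435). That call was lost without any 1 of the 6 libraries. Its edgeR adjusted p was 0.087 without Surface 1, 0.146 without Surface 2, 0.0571 without Tinaja 1, 0.146 without Tinaja 2, 0.107 without Pachon 1 and 0.105 without Pachon 2. It was 0.0974 with only the populations compared in the fit and 0.0949 with the replicate block, the highest over its alternatives being 0.146. For ENSAMXG00000025561 the edgeR adjusted p was 0.0726 without Surface 1, its highest, 0.063 without Surface 2 and 0.0504 with total-count scaling. The count of called genes was 1277 without Surface 1, 1303 without Surface 2, 1126 without Tinaja 1 and 878 without Tinaja 2.

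Both caves differed from Surface on the same side in 1175 genes, 541 higher and 634 lower. Independent lists of these sizes would share 109.2 higher and 94.9 lower genes. Unchanged groups simulated with a shared Surface group shared 0.6 on average and 4 at most. Those simulations made only 2.85 calls per comparison on average. Lists so short cannot show how many genes shared controls add to lists of the observed size. Another 44 genes lay on opposite sides. Across all tested genes the log2 fold changes of both caves had a Pearson correlation of 0.586, against 0.503 (0.475 to 0.527) in the simulations, and a covariance of 1.266 against 0.101, a difference of 1.165. A split of the Surface libraries would leave 1 in each part and was not made, so part of the excess of shared calls may come from the shared controls. Of the 1175 genes, 1055 did not differ between the caves by the test and 120 did. With total-count scaling 840 genes were higher and 395 lower in both caves. The count of shared genes was 589 without Pachon 1, 548 without Pachon 2, 625 without Surface 1, 691 without Surface 2, 562 without Tinaja 1 and 598 without Tinaja 2.

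**Figure D1:**
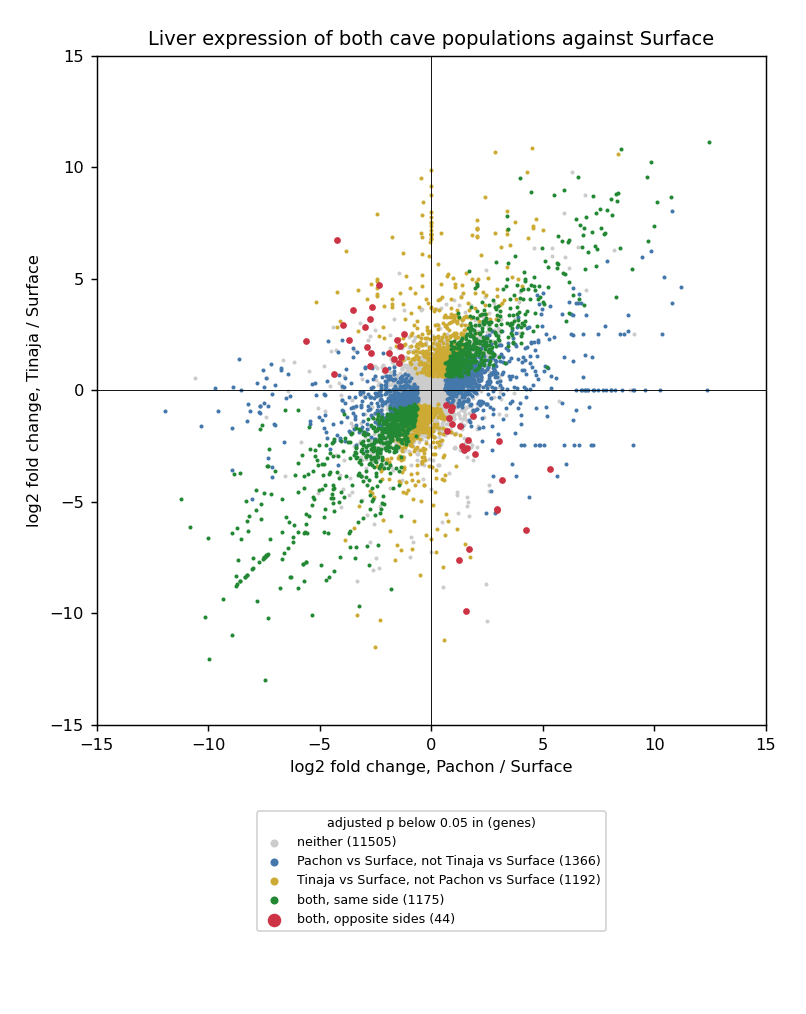
Log2 fold change of Pachon over Surface (horizontal) and of Tinaja over Surface (vertical) for the 15282 tested genes, 1 point per gene, coloured by which comparison called it. The 1175 genes called on the same side lie in the lower left and upper right quadrants, and the 44 called on opposite sides in the other quadrants.

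The mean of both caves differed from Surface in 2713 genes (17.8%), 1257 higher and 1456 lower in the caves, with a median log2 fold size of 1.42 (median SE 0.26). Of the called genes, ENSAMXG00000015502 was highest by fold. It had a ratio of 5278 from the reads pooled over the 4 cave libraries, with a counting interval of 947 to 208474 (edgeR adjusted p = 0.000504). Its fitted log2 fold change was 11.8, against 10.89 without Surface 1 and 14.28 without Surface 2. Among called genes that met the rule for named genes, ENSAMXG00000025561 rose most in CPM. Its log2 fold change was 6.6 ± 1.04 (SE, edgeR adjusted p = 0.00936), or 5.59 without Tinaja 1. The gene lowest by fold had 20.4 CPM ± 3.34 (SD, n = 2) in Surface, 1 read in Pachon and 0 in Tinaja, a ratio of 2219 from the pooled cave reads with a counting interval of 397 to 87722 (edgeR adjusted p = 9.82e-05), and a fitted log2 fold change of -11.01, against -11.93 without Pachon 2. The gene with the largest fall in CPM was the one with the largest fall in Tinaja. It had 31542.4 CPM ± 3003.5 (SD, n = 2) in Pachon and was not called there (edgeR adjusted p = 0.0753). For the mean of both caves its log2 fold change was -1.4 ± 0.34 (SE, edgeR adjusted p = 0.0284). Its edgeR adjusted p was 0.125 without Pachon 1, 0.109 without Pachon 2, 0.0729 without Surface 1, 0.141 without Surface 2, its highest, and 0.0674 with the replicate block. That of ENSAMXG00000025561 was 0.0592 without Surface 1, its highest, and 0.0523 without Surface 2. The count of called genes was 1807 without Pachon 1, 1657 without Pachon 2, 1485 without Surface 1 and 1460 without Surface 2. Total-count scaling moved the median of all genes to 0.319 and the higher share of the calls from 46.3% to 72.9%.

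The caves differed from each other in 1409 genes (9.2%), 683 higher and 726 lower in Pachon, with a median log2 fold size of 1.94 (median SE 0.33). Of these, 197 were at least 8-fold higher and 220 at least 8-fold lower. ENSAMXG00000042564 was lowest by fold and fell most in CPM, with 1.13 CPM ± 0.342 in Pachon and 2281.7 ± 1603.4 in Tinaja (SD, n = 2), a log2 fold change of -10.98 ± 0.8 (SE, edgeR adjusted p = 0.000643). The value was -9.96 without Tinaja 1 and -11.57 without Tinaja 2. The gene highest by fold had 25.3 CPM ± 1.39 (SD, n = 2) in Pachon and 0 reads in both Tinaja and Surface, at least 363-fold higher than the Tinaja floor (edgeR adjusted p = 0.000642). Under the same rule, the called gene with the largest excess in CPM had 4019.8 ± 601.8 in Pachon and 853.3 ± 28.1 in Tinaja (SD, n = 2). Its log2 fold change was 2.24 ± 0.46 (SE, edgeR adjusted p = 0.0281). Its edgeR adjusted p was 0.0869 without Pachon 1, 0.131 without Pachon 2, 0.0944 without Tinaja 1 and 0.151 without Tinaja 2, its highest. The count of called genes was 505 without Pachon 1, 380 without Pachon 2, 890 without Tinaja 1 and 352 without Tinaja 2. With total-count scaling, which moved the median of all genes to 0.478, it was 2771, 2300 higher and 471 lower, or 83% higher against 48.5%.

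Among the most abundant liver transcripts, those that differed from Surface were mostly lower in each cave, while most passed no test. Of the 173 genes with a mean of at least 1000 CPM, 40 were lower and 2 higher in Pachon, and 33 lower and 2 higher in Tinaja. Between Pachon and Tinaja, 3 were higher and 1 lower in Pachon. Of the 729 genes from 100 to 1000 CPM, 112 were lower and 65 higher in Pachon, and 98 lower and 60 higher in Tinaja. From 1 to 10 CPM, 498 of 7246 genes were lower and 620 higher in Pachon, and 498 lower and 598 higher in Tinaja. The median log2 fold change of the 173 genes against Surface was -0.69 in Pachon, with 144 below 0, and -0.27 in Tinaja, with 127 below 0. For Pachon against Tinaja it was -0.4, with 121 below 0. These medians depend on the scaling and were not recomputed with total counts. That scaling moved the median of all genes against Surface to 0.55 in Pachon and 0.084 in Tinaja. With total-count scaling 27 were lower and 10 higher in Pachon, and 30 lower and 2 higher in Tinaja. The count of lower genes in Pachon was 6 without Pachon 1, 6 without Pachon 2, 15 without Surface 1 and 27 without Surface 2. In Tinaja it was 14 without Tinaja 1, 10 without Tinaja 2, 15 without Surface 1, 17 without Surface 2, 18 without Pachon 1 and 18 without Pachon 2.

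**Figure D2:**
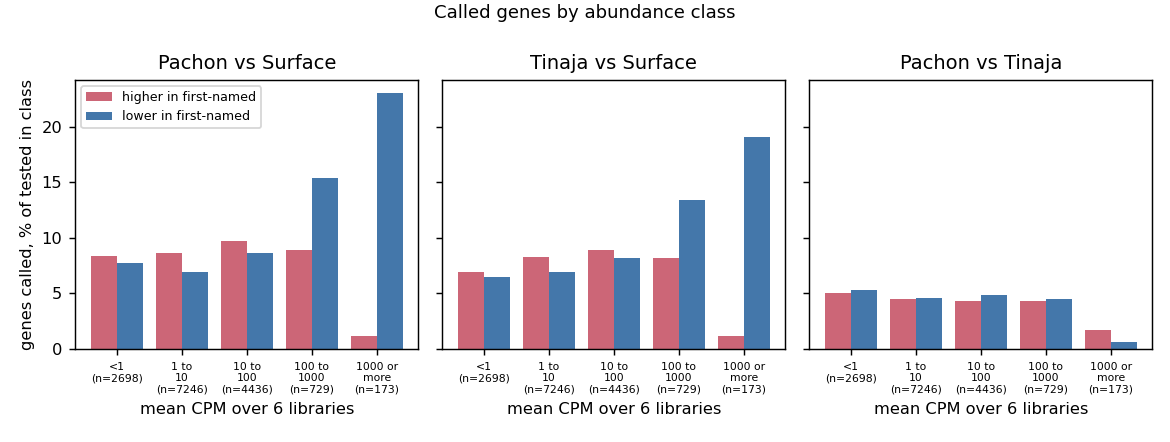
Share of tested genes called higher (red) or lower (blue) in the first-named population, by mean CPM over the 6 libraries, with the number of genes tested under each class. At 1000 CPM or more, 40 of 173 genes were lower and 2 higher in Pachon than in Surface, and 33 lower and 2 higher in Tinaja.

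A group of abundant genes differed several-fold between libraries of the same population. ENSAMXG00000038452, the most abundant gene of the table, had 13538.1 and 1339.0 CPM in Surface 1 and 2, 33928.6 and 3445.5 in Pachon 1 and 2, and 81750.6 and 193738.7 in Tinaja 1 and 2. ENSAMXG00000017475 and ENSAMXG00000017461 moved with it: the log2 differences of replicate 1 from 2 were 3.34, 3.21 and 3.4 for the 3 genes in Surface, 3.3, 3.34 and 3.35 in Pachon, and -1.24 for each in Tinaja. None of the 3 passed edgeR's test in a pairwise comparison, with adjusted p from 0.0918 to 0.567. A set of 10 genes differed between replicates in these directions by at least 2 on the log2 scale in Surface and Pachon and 0.5 in Tinaja, a rule set after the values were seen. It took 2.25% and 0.25% of the counts in Surface 1 and 2, 9.68% and 1.04% in Pachon 1 and 2, and 18.63% and 36.45% in Tinaja 1 and 2. With the set included, the 173 genes of at least 1000 CPM took 64.8% and 64.1% of all counts in Surface 1 and 2, 57.8% and 53.5% in Pachon 1 and 2, and 62.8% and 69.9% in Tinaja 1 and 2, so that the Tinaja libraries lay on either side of Surface. Outside this set, the other 168 genes of at least 1000 CPM took 64.1% ± 0.1 of the remaining counts in Surface, 53.3% ± 0.25 in Pachon and 53.7% ± 1.02 in Tinaja (SD, n = 2). All 4 cave libraries, at 53% to 54.4%, lay below both Surface libraries (exact permutation test, two-sided p = 0.067 over 15 splits, the smallest this design allows).

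**Figure D3:**
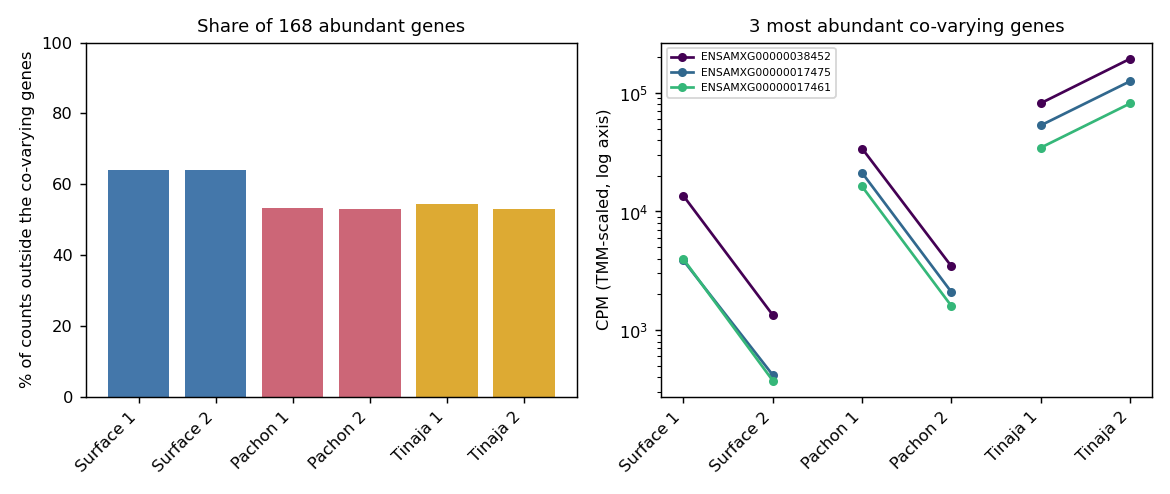
Left, percent of the counts outside the 10 co-varying genes that 168 genes of at least 1000 CPM took in each library; right, CPM on a log axis of the 3 most abundant co-varying genes per library, with lines joining libraries of a population. Surface libraries average 64.1% and cave libraries lie between 53% and 54.4%, and the 3 genes move together between replicates.

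Some genes were on in one population and off in another. Between Pachon and Surface, 65 were on in Pachon and off in Surface and 52 the reverse; between Tinaja and Surface the numbers were 51 and 57, and between Pachon and Tinaja 55 and 47. Of these, in the same order, 64, 52, 49, 54, 51 and 43 passed edgeR's test. The genes were chosen from the same counts, so most were bound to pass and the test is no separate support. On in both caves and off in Surface were 16 genes, and 28 were on in Surface and off in both caves. Counts of near-identical gene copies may be split between identifiers in a way the sources used here do not describe.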

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

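The tests of explanations here were chosen only after the results were seen; the comparison of Pachon with Tinaja was planned.

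Both caves were called against Surface on opposite sides in 44 genes, and all 44 also differed between the caves. The latter was nearly bound to follow, since the difference between the caves spans both differences from Surface, and is no separate support. ENSAMXG00000042564 drew attention because the caves differed from each other by -10.98 ± 0.8 on the log2 scale (SE, edgeR adjusted p = 0.000643), with -9.96 without Tinaja 1 and -11.57 without Tinaja 2. Pachon was lower than Surface by -11.92 ± 0.82, while Tinaja differed by -0.94 ± 0.52 (edgeR adjusted p = 0.261). For ENSAMXG00000038681 both caves were lower than Surface, and Pachon exceeded Tinaja by 5.52 ± 0.52 (SE, edgeR adjusted p = 0.00154). The gene read in Pachon and at 0 reads in Surface and Tinaja had a fitted log2 difference between the caves of 12.35, a value that depends on the prior count; its bound is at least 363-fold. The gene with the largest CPM excess of Pachon over Tinaja among the called genes differed between the caves by 2.24 ± 0.46 (SE, edgeR adjusted p = 0.0281). Pachon differed from Surface there by 0.15 ± 0.44 (edgeR adjusted p = 0.85) and Tinaja by -2.09 ± 0.46 (edgeR adjusted p = 0.0242).

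Genes on in one population and off in another were weighed as a pattern. Against Surface, 100 genes were on in a cave and off in Surface, and 81 were off in a cave. For the 81, cave reads that map poorly to a surface-fish genome stay open as an explanation, since they made up 44.8% of both kinds, each gene counted once (exact 95% interval 37.4 to 52.3, with the same Surface libraries behind both caves). Reads passed between near-identical gene copies and differences of gene content between populations were not tested and may apply as well.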

How the results depend on the processing

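Total-count scaling and the count of lower genes at 1000 CPM or more were chosen after the data were seen; the other settings were planned. Of 260 values for the 15 named results under other settings, 229 kept their call and direction, 31 lost the call and 0 reversed. The stricter threshold and the 2-fold bound reread the main fit, so their values could not reverse. All 15 results exceeded 2-fold in the main fit, so that bound could not cost a call. Counts of called genes are given in the order Pachon and Surface, Tinaja and Surface, Pachon and Tinaja, cave mean, both caves, where all 5 apply. At an adjusted p below 0.01 they were 845, 650, 328, 998 and 313, and lower genes of at least 1000 CPM were 8 in each cave. With a mean CPM of at least 5 they were 1404, 1320, 526, 1623 and 668, with fewer genes tested. Leaving out 1 library, which leaves fewer samples, gave 937 to 2318, 878 to 1812, 352 to 1360, 1460 to 2028 and 548 to 691, and lower abundant genes of 6 to 40 in Pachon and 10 to 18 in Tinaja. DESeq2 called 63 abundant genes lower and 9 higher in Pachon, and 56 lower and 10 higher in Tinaja. The main fit called 40 lower and 2 higher in Pachon, and 33 lower and 2 higher in Tinaja. The fit of only the populations compared called 19 lower and 3 higher in Tinaja. The cause was not tested. Total-count scaling called 4599 genes between Pachon and Surface and 2771 between the caves, where it moved the median of all genes as described above. The other planned settings kept these counts within 1.5 times.

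Deviations of same-numbered libraries correlated across genes at 0.024, 0.024 and -0.104 in the 3 pairs of populations. No pairing by replicate number was thus seen over all genes, though a factor shared by same-numbered libraries in some genes cannot be excluded this way. With the replicate block the counts were 2136, 1956, 1043, 2259 and 959, and lower abundant genes 33 and 23. The gene list tests, with their alternatives, and the removal of egg protein genes were not run for want of symbols; the setting without abundant genes left out the top 20 alone. Depth left 99.95% of reads in tested genes. The simulations recovered 7% of 2-fold changes in Pachon and 8.8% in Tinaja. They changed only 200 genes, far fewer than were called here, so these shares do not measure recovery in the data.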

Other observations

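All tests of explanations here were chosen after the results were seen.

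Each cave had genes that differed from both other populations. Pachon was called against both Surface and Tinaja, with Tinaja not called against Surface, in 504 genes, 295 higher and 209 lower. Tinaja was called against both Surface and Pachon, with Pachon not called against Surface, in 445 genes, 290 higher and 155 lower. All 3 pairs were called in another 120 genes with the caves on the same side of Surface and 44 with them on opposite sides. Surface stood apart from both caves, which did not differ by the test, in 1055 genes, 479 with the caves higher and 576 with them lower. In all, 4073 genes (26.7%) were called in some pairwise comparison.

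The excess of lower over higher calls among abundant genes in both caves was weighed against scaling and single libraries. With total-count scaling 73% of the called genes of at least 1000 CPM were lower in the cave where the share was smaller, with the 20 most abundant genes left out 96.7%, without Surface 1 88.2%, without Surface 2 93.1%, without Tinaja 1 87.5% and without Tinaja 2 83.3%. The exact 95% intervals lay above 50% in both caves in each of these cases. They treat genes as independent, which genes of the same libraries are not, so they do not measure the spread between libraries. The lower share itself stayed above 50% in each case. That argues against TMM scaling, the top 20 genes or any 1 of those libraries as the whole cause. Without either Pachon library only 6 lower and 2 higher genes were called in Pachon (75%, 34.9 to 96.8), but abundant genes outside the co-varying set took 53.4% of the other counts in Pachon 1 and 53.1% in Pachon 2, against 64.1% and 64.0% in Surface 1 and 2, which argues against a single Pachon library. A population difference in how the liver spreads its transcripts over genes is a candidate explanation, and feeding, sex and RNA handling, which the labels do not give, stay open and untested.

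The 10 co-varying genes were weighed as well. For the most abundant gene, ENSAMXG00000038452, and the 2 nearest to it, unrelated replicate differences are argued against: ENSAMXG00000017461 lay within 0.06 and ENSAMXG00000017475 within 0.13 on the log2 scale in every population, against medians of 0.76 and 1.01 for the nearest and the second nearest when the differences of the 24 genes with such large values of any sign were permuted over genes (100000 permutations, permutation p = 0.0115 and 5e-05). For the other 7 members they cannot be told apart from a shared change, since 10 genes had the sign pattern of the most abundant one and 6 the next most common pattern. A single transcript pool split over identifiers in 1 fixed ratio is argued against by the log2 ratio of ENSAMXG00000017475 to ENSAMXG00000038452, which was 1.08 higher in the caves than in Surface and differed by at most 0.13 within a population, though a split that depends on the population stays open. RNA of another tissue carried into the liver sample in differing amounts may also give such a set of 10 genes, and cannot be told apart without gene names to look up its markers.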
